A study of Arabidopsis thaliana with 12 samples.

How the data were processed

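Gene expression was measured by RNA sequencing in the shoots of Arabidopsis thaliana plants of 4 genotypes, with 3 libraries per genotype and 12 in all. The genotypes were the wild-type accession Col-0 and the mutants hda6, nrpd1-3 and ros1-4. Per the labels' protocols, plants were 2 weeks old and grown at 22 °C with 16 h of light and 8 h of dark, total RNA was extracted with a column kit, libraries were made with a commercial RNA-seq kit and sequenced on an Illumina instrument. Roots and stems, which the growth protocol also mentions, were not analysed here. Each sample's title gave its genotype and its replicate number. The labels do not say whether the replicates are separate cultures or pools of plants, so p-values here measure only the spread between these samples, which may be technical.

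The submitters' processing notes name FastQC, HISAT2, SAMtools and edgeR, without versions, and the TAIR10 genome build. The counting program, the annotation it used, the handling of strand and the way read pairs were counted are not given in the sources used here. The deposited count table held raw counts of 36589 features in whole numbers, with no normalization by the authors. Of these, 3911 were numbered variants of a locus that held no count in any library, and the other 32678 were loci. A second deposited table held a signal for the 24440 loci with a count in some library. It equalled the deposited count divided by the library total times 1 factor per library, scaled as CPM, and its library sums ran from 960669 to 1042500. The counts recovered from it differed from the deposited counts by at most 0.00808. Between 73.8% and 77.5% of the counts above 0 in a library were even numbers, so both mates of a pair seem to have been counted separately, and counts are then not independent reads.

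Loci were joined by identifier to the TAIR10.1 annotation, whose nuclear sequence is that of TAIR10; 31912 loci matched, and the unmatched ones held 0.0965% of the counts. Coordinates are in that build. Of 3910 loci annotated as pseudogenes, a class that includes transposon genes, 2 had a count above 0, so transposon transcription was not analysed here. The library totals ran from 23803721 to 41222299 counts. Intervals and floors cover counting error only, since reads without molecular identifiers can be PCR copies. Of the tested gene models, 31.5% overlap another gene on either strand, introns included, and strand is not stated. Reads in the shared stretches cannot be assigned with certainty, and this holds for named genes said to overlap another gene.

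The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr at its default minimum count of 10 and minimum total of 15, which left 20023 genes. All 12 libraries entered 1 model with a mean per genotype and 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed, and a second count took those changed at least 2-fold, a log2 fold change of 1 or more in size. Levels are TMM-normalised CPM (reads counted for the gene relative to the scaled library total), given as mean ± SD of 3 libraries. Log2 fold changes are given with a standard error (SE), the size of the fold change divided by the square root of the test's F statistic. This SE was not estimated directly by the fit and may be too small for genes with few counts in a group. With 3 libraries against 3, an exact permutation test of a single gene cannot give a two-sided p below 0.1, so the p-values rest on the model's pooling of the spread over genes. Where a group had no count, the fold was computed against a floor of 3 counts over the group's 3 libraries and is a lower bound. It takes counts pooled over the 3 libraries of each genotype relative to their pooled totals, so it can differ slightly from the ratio of the mean CPM to the floor. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval. Both take counts as independent; if both mates of each pair were counted, the lower bounds would be 2 times smaller and the intervals wider.

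Before the data were examined, 22 gene lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed. The lists covered the pathways of DNA demethylation, RNA-directed DNA methylation and the maintenance of DNA and histone H3K9 methylation, histone deacetylases, loci known to be silenced by DNA methylation, loci known to need ROS1, the FLC clade with floral integrators, photosynthesis, the salicylic acid, jasmonate, abscisic acid with cold, and heat shock responses, the circadian clock (for harvest time), touch and wound genes (for handling), iron deficiency, phosphate starvation, anthocyanin, glucosinolate, DNA replication with mitosis, and markers of root, seed and floral organs. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation. Named genes were ROS1, NRPD1, HDA6, the silenced loci, the loci known to need ROS1, FLC, MAF4 and MAF5. To these came the 10 largest rises and 10 largest falls per comparison with Col-0 by fitted log2 fold change. They came from changed genes with no overlap between the libraries of both genotypes and a mean of at least 1 CPM over all 12 libraries. Up to 4 changed members per list, up to 3 per annotation class and up to 5 per overlap set, by smallest p, were added. Against a group with no count the fitted value served only to choose genes and gives no order. Not every gene of these sets is named in the text. Genes changed in opposite directions, genes at 0 in a single genotype and the sugar starvation list were chosen after their values were seen.

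The model and, for hda6 against Col-0 alone, camera were tested on simulated counts with 200 changed genes among 20023. For hda6 against Col-0, 34.3% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 90.9% of those changed 4-fold were called, and 5.76% of the calls were false. For nrpd1-3 the shares called were 37.3%, 73.1% and 98.5%, with 2.11% false, and for ros1-4 41.8%, 85.1% and 95.5%, with 9.76% false. Overlaps between mutants were set beside 50 simulations of unchanged genotypes against the same Col-0 libraries.

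The alternatives were size factors as in DESeq2 (RLE) or library size alone in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, the pair of genotypes alone, the replicate number as a block, limma-trend on log2 of the deposited signal plus 1, organelle genes left out, the robust quasi-likelihood fit and leaving out each replicate in turn. After the data were seen, counts halved, a correction for exon length by a spline per library, and the omission of hda6 replicate 2, nrpd1-3 replicate 3 and ros1-4 replicate 3 together were added.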

Results

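The data are gene counts from shoots of 2-week-old Arabidopsis plants of 4 genotypes, with 3 libraries each. The title of the series names ROS1, a DNA glycosylase that removes 5-methylcytosine, as a marker and regulator of accessible chromatin. The ros1-4 mutant lacks its function. NRPD1 is the largest subunit of RNA polymerase IV, which starts RNA-directed DNA methylation, and HDA6 is a histone deacetylase that acts in gene silencing. Library totals were 27176634, 35343144 and 24023195 counts for Col-0, 41222299, 32560586 and 28539976 for hda6, 28336682, 29297865 and 23803721 for nrpd1-3, and 27365409, 25322988 and 31220464 for ros1-4. Between 21346 and 22534 loci per library had a count above 0. Within genotypes, log2 CPM correlated between libraries at 0.973 to 0.993 across genes. No pair of libraries differed by as little as sampling noise, with a chi-square per gene of 5.23 at the least.

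In 3 libraries short transcripts were lowest relative to the other libraries of the genotype. The median deviation of the 1137 genes with the least exon length, among 12672 well-read genes, was -0.338 on the log2 scale in nrpd1-3 replicate 3, -0.238 in ros1-4 replicate 3 and -0.0663 in hda6 replicate 2. It was -0.0216 in hda6 replicate 3 and -0.0176 in Col-0 replicate 1. Thus hda6 replicate 2 lay nearer to these than to replicate 3 of nrpd1-3 and ros1-4. Organelle genes took 0.257% of the counts in nrpd1-3 replicate 3 and 0.0476% to 0.0807% in the other 11 libraries.

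ROS1 (AT2G36490, chromosome 2, 15307907 to 15314807) stood at 82.5 ± 3.22 CPM in Col-0. It fell to 30.3 ± 1.44 CPM in hda6, a log2 fold change of -1.45 ± 0.13 (SE, adjusted p = 3.59e-06), and to 3.26 ± 0.705 CPM in nrpd1-3, a log2 fold change of -4.67 ± 0.16 (adjusted p = 2.46e-10). The hda6 and nrpd1-3 levels also differed from each other, 9.34-fold (adjusted p = 4.88e-09). In ros1-4 the gene was read at 74.1 ± 12.5 CPM, with a log2 fold change of -0.15 ± 0.13 (adjusted p = 0.502). Without the 3 libraries low in short transcripts the edgeR test called it lower in ros1-4 (-0.30, adjusted p = 0.0401). The ros1-4 allele is an insertion, so reads over the whole gene do not check that label, and the same holds for NRPD1 in nrpd1-3. NRPD1 (AT1G63020, chromosome 1, 23354685 to 23362589) was read at 11.6 ± 0.945 CPM in Col-0, 10.8 ± 0.269 in hda6, 9.60 ± 0.904 in nrpd1-3 and 8.67 ± 1.56 in ros1-4, and none of the 6 pairs of genotypes passed the main test, with adjusted p-values from 0.0544 to 0.635. The call for NRPD1 in ros1-4 against Col-0 (log2 fold change -0.41) depended on the setting. It passed without ros1-4 replicate 3 (-0.54, adjusted p = 0.02003), with library size alone (adjusted p = 0.0487), with the replicate block (0.0302), with the length correction (0.00938) and without the 3 libraries low in short transcripts (0.00910), and stood at -0.27 without ros1-4 replicate 1 (adjusted p = 0.227). Without ros1-4 replicate 3 NRPD1 also differed between hda6 and ros1-4 (adjusted p = 0.0379), and without those 3 libraries NRPD1 was lower in nrpd1-3 than in Col-0 (adjusted p = 0.0435). HDA6 (AT5G63110, chromosome 5, 25315506 to 25318347) was higher in hda6, at 30.4 ± 2.66 CPM against 23.3 ± 0.662 in Col-0, a log2 fold change of 0.38 ± 0.09 (adjusted p = 0.0102; 0.0527 without hda6 replicate 2). It overlaps another gene, and the hda6 allele is not given in the sources used here.

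**Figure D1:**
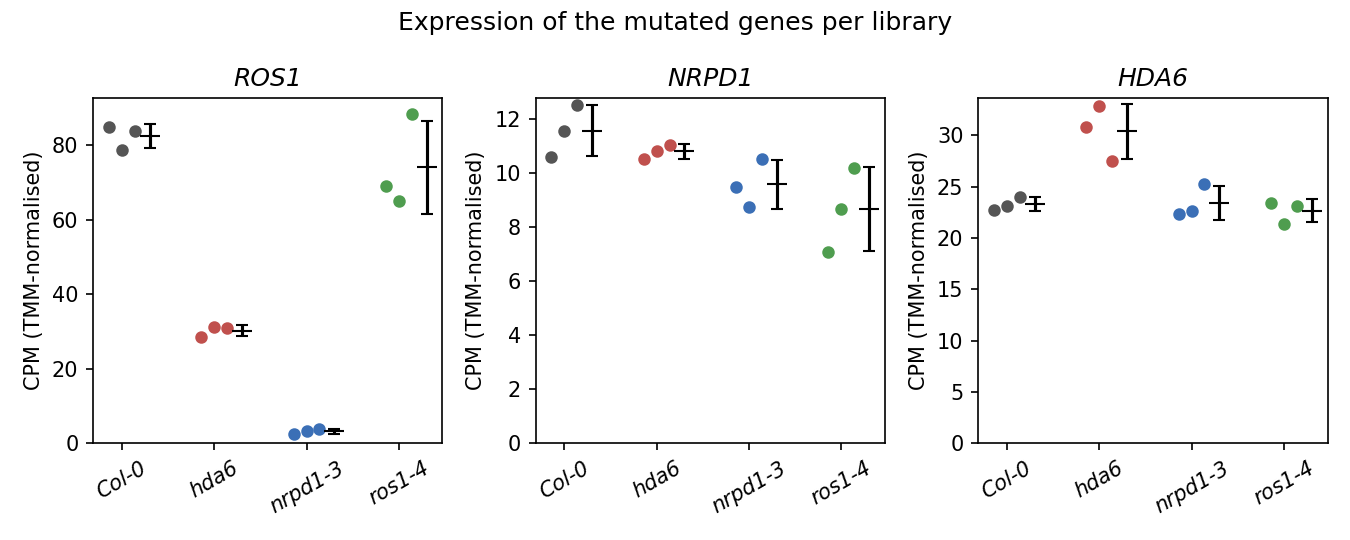
TMM-normalised CPM of ROS1, NRPD1 and HDA6 in each of the 12 libraries, as points by genotype, with bars for the mean and SD of the 3 libraries. ROS1 lay between 2.53 and 3.93 CPM in the nrpd1-3 libraries and between 78.8 and 84.8 CPM in the Col-0 libraries.

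In hda6, loci known to be silenced by DNA methylation and several genes without any count in Col-0 were transcribed. AT3G01345 (chromosome 3, 129138 to 130749) rose from 0.167 ± 0.0887 to 523.9 ± 82.6 CPM, the F-box gene SDC from 0.591 ± 0.181 to 24.2 ± 0.796 CPM, and the starch regulator QQS from 4.1 ± 0.495 to 57.7 ± 11.7 CPM. PR1, a marker of the salicylic acid response, fell from 36.0 ± 4.45 to 0.764 ± 0.194 CPM. The 12 tested touch genes fell with it, as did 13 of 22 abscisic acid and cold genes and 12 of 20 jasmonate genes. In all, 3991 of 20023 genes were changed in hda6, 1949 higher and 2042 lower, and 704 of the higher and 625 of the lower genes changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg).

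Several genes with no count in the Col-0 libraries were read in hda6; their folds are lower bounds and give no order among rises. AT5G41660 (chromosome 5, 16656708 to 16658405) reached 129.2 ± 13.8 CPM, at least 3708-fold higher than in Col-0. AT4G08593 reached 91.5 ± 6.10 CPM (at least 2606.5-fold) and AT5G03090 77.0 ± 4.66 CPM (at least 2195-fold). AT5G45570, annotated as a Ulp1 protease family gene, reached 75.9 ± 1.18 CPM (at least 2148-fold), and the noncoding RNAs AT2G15555 and AT2G01422 reached 54.8 ± 4.81 and 43.8 ± 6.06 CPM. OFP9 of the ovate family of repressors reached 32.6 ± 0.695 CPM, at least 924-fold higher. All 4 tested members of the list of loci silenced by DNA methylation rose, with a median log2 fold change of 4.56 (camera adjusted p = 6.58e-07; 4 higher adjusted over the list alone). They were AT3G01345 (11.6 ± 0.30 SE), SDC (5.31 ± 0.22; it overlaps another gene), QQS (3.82 ± 0.24) and AT1G59930 (2.46 ± 0.38). FWA, HDG3 and DOGL4 had too few counts in the 12 libraries to be tested in any comparison.

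Among flowering genes, the repressors FLC, MAF4 and MAF5 rose in hda6, with log2 fold changes of 2.36 ± 0.21, 2.63 ± 0.14 and 2.51 ± 0.18. FLC, which overlaps another gene, stood at 12.1 ± 1.46 CPM against 2.37 ± 0.458 in Col-0. The floral integrator SOC1 fell by 1.04 on the log2 scale, to 9.38 ± 0.977 CPM (adjusted p = 3.43e-05). With 3 members higher and 3 lower among 11, the list of the FLC clade and floral integrators did not pass camera (adjusted p = 0.907).

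Of 12 tested touch and wound genes, 12 fell in hda6 (12 adjusted over the list alone), with a median log2 fold change of -2.21 (camera adjusted p = 2.04e-16). WRKY40 fell from 81.0 ± 1.95 to 5.91 ± 1.23 CPM, the zinc finger gene ZAT10 from 159.7 ± 30.9 to 34.8 ± 2.21, and TCH4, a touch-induced xyloglucan endotransglucosylase, from 405.8 ± 10.6 to 136.4 ± 5.01. Genes of this list respond to handling, and they moved with the following stress groups. Of 22 abscisic acid and cold genes 13 fell (14 adjusted over the list alone; median -0.85, camera adjusted p = 6.74e-08), including the abscisic acid synthesis gene NCED3 with a log2 fold change of -3.48 ± 0.14 and the cold regulator CBF1 with -4.24 ± 0.24. Of 20 jasmonate genes 12 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.99, camera adjusted p = 6.47e-06). The jasmonate hydroxylase CYP94B3 fell by 5.24 and the regulator MYC2 by 1.71 on the log2 scale. ORA47, which acts on jasmonate synthesis, went from 134.4 ± 2.33 to 7.82 ± 0.179 CPM. Of 24 salicylic acid genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.82, camera adjusted p = 7.24e-07), with a log2 fold change of -5.53 ± 0.21 for PR1 and a fall of WRKY18 from 46.4 ± 2.92 to 16.4 ± 0.550 CPM. WRKY40, MYC2, ORA47 and, below, IMA3 overlap another gene.

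Nutrient genes moved in both directions in hda6. Of 12 iron deficiency genes 8 fell (9 adjusted over the list alone; median -0.89, camera adjusted p = 4.82e-05), among them the iron peptide gene IMA3 (-2.61 ± 0.30) and the transcription factor BHLH100 (-2.38 ± 0.35). Of 8 phosphate starvation genes 7 rose (8 adjusted over the list alone, median 0.72, camera adjusted p = 1.95e-05). Among them were the galactolipid synthase MGD3 (3.37 ± 0.39) and the phosphate sensor SPX1 (1.28 ± 0.18). Of 16 glucosinolate synthesis genes 9 fell (9 adjusted over the list alone; median -0.43, camera adjusted p = 3.41e-06), including CYP79B3 (-0.79 ± 0.07) and MAM1 (-0.62 ± 0.07). The clock list passed with a median of 0.19 (4 of 13 genes higher, 4 adjusted over the list alone; camera adjusted p = 0.0289), and adjusted p = 0.277 with an estimated correlation. The call also ended without the 3 libraries low in short transcripts and with the length correction.

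The other lists did not pass in hda6, with camera adjusted p-values from 0.189 to 0.984. In RNA-directed DNA methylation 4 of 27 genes were higher and 1 was lower; the Argonaute genes AGO6 and AGO9 rose by log2 fold changes of 1.08 ± 0.19 and 1.82 ± 0.34. In methylation maintenance 1 of 12 genes fell, the histone demethylase gene IBM1 (-0.79 ± 0.15), and in demethylation 1 of 13 fell, ROS1. Among histone deacetylases 2 of 13 were higher and 2 lower (3 and 4 adjusted over the list alone). Of the other groups, 3 of 25 photosynthesis genes were higher and 2 lower, 1 of 8 heat shock genes was higher and 1 lower (2 and 1 over the list alone), 1 of 11 anthocyanin genes was higher and 2 lower (2 and 3 over the list alone), 1 of 18 replication and mitosis genes was higher, and none of 3 loci known to need ROS1 was called. Of markers of other organs, 0 of 4 root genes and 2 of 5 floral organ genes were called, both lower, and FUS3, the single tested seed marker, was higher (2.32 ± 0.50, adjusted p = 0.00509).

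Genes higher in hda6 lay near centromeres more often than other tested genes. Within 3 Mb of a centromere lay 251 of 1938 higher genes on the nuclear chromosomes, 13.0%, against 7.78% of the others (odds ratio 1.76, 95% interval 1.52 to 2.04; Fisher's exact test, two-sided, adjusted p = 9.46e-13). For lower genes the share was 7.36% against 8.39% (adjusted p = 0.175). A gene silent in Col-0 was tested only if another genotype had enough reads of it. Genes that stayed silent are therefore missing from the others, which can raise the odds ratio for higher genes. The test also takes neighbouring genes as independent. Of 179 tested noncoding RNA genes 23 were higher and 3 lower; the higher share, 12.8%, did not differ from the 9.71% of other genes (Fisher's exact test, adjusted p = 0.237), and the lower share was below theirs (adjusted p = 7.88e-05). The noncoding RNA AT2G05914, which overlaps another gene, rose from 0.152 ± 0.130 to 61.8 ± 5.02 CPM. With the length correction 2656 genes were higher and 1837 lower, so 59.1% of the changed genes were higher, a share 10.3 percentage points above that of the main test. Without hda6 replicate 1, 2639 genes passed, below the main count by more than 1.5 times.

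**Figure D2:**
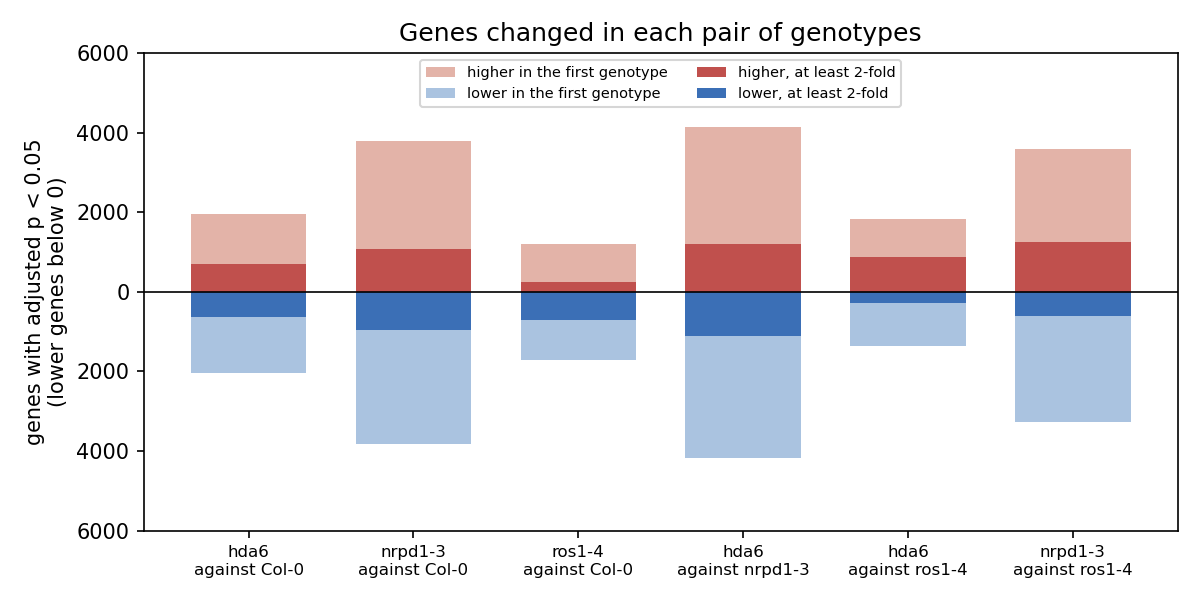
Number of genes with an adjusted p under 0.05 in each of the 6 pairs of genotypes, higher genes above 0 and lower genes below, with those changed at least 2-fold in darker colour. The counts ran from 2904 for ros1-4 against Col-0 to 8313 for hda6 against nrpd1-3.

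In nrpd1-3, 11 of 12 iron deficiency genes and the 11 tested anthocyanin genes fell. So did 7 of 8 heat shock genes, though the call of that list was lost with an estimated correlation (adjusted p = 0.106). The asparagine synthetase gene ASN1, which is induced in darkness, rose from 0.246 ± 0.170 to 71.4 ± 7.24 CPM (log2 fold change 8.09 ± 0.26; it overlaps another gene) and the senescence gene SEN1 (AT4G35770) from 0.636 ± 0.367 to 68.9 ± 4.28 CPM (6.75 ± 0.26). The heat stress factor HSFA2 fell from 54.2 ± 6.98 to 0.683 ± 0.317 CPM, a log2 fold change of -6.30 ± 0.21. ROS1 was among the 10 largest falls by fitted fold. In all, 7626 of 20023 genes were changed, 3797 higher and 3829 lower, of which 1084 and 962 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg).

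Some genes without a count in Col-0 were read in nrpd1-3. The noncoding RNA AT2G01422 (chromosome 2, 183940 to 184734) reached 9.04 ± 2.1 CPM, at least 260.2-fold higher than in Col-0, AT2G10975 reached 5.24 ± 0.740 CPM (at least 147-fold), and AT5G41830 reached 1.88 ± 0.129 CPM (at least 53.3-fold). AT1G33840 rose from 0.121 ± 0.0875 to 28.8 ± 6.32 CPM and AT3G29639 from 0.450 ± 0.130 to 73.6 ± 6.77 CPM. Among the large falls were the chaperone gene HSP70-4, from 217.1 ± 11.9 to 10.8 ± 2.31 CPM, the sugar transporter gene SAG29, from 56.9 ± 3.79 to 3.32 ± 0.603 CPM, and BHLH100, from 3.39 ± 0.264 to 0.101 ± 0.0578 CPM. AT5G66150 had no count in nrpd1-3 and 0.292 ± 0.189 CPM in Col-0, at least 8.18-fold lower.

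Of the 4 tested loci silenced by DNA methylation, 3 rose in nrpd1-3 and QQS fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.106). SDC reached 8.57 ± 0.790 CPM (3.81 ± 0.22 SE), AT3G01345 0.727 ± 0.387 CPM (2.06 ± 0.46), and AT1G59930 1.80 ± 0.635 CPM (1.94 ± 0.39), while QQS went to 1.1 ± 0.527 CPM (-1.87 ± 0.29). Of the 3 loci known to need ROS1, the disease resistance gene RMG1 rose (1.64 ± 0.45, adjusted p = 0.0104; 0.0554 without Col-0 replicate 2), and EPF2, which limits stomatal density, and RLP43 were not called, with log2 fold changes of -0.36 ± 0.34 and 0.32 ± 0.38. FLC rose to 9.36 ± 1.86 CPM (1.99 ± 0.21), MAF3 by 1.29 ± 0.14 and MAF4 by 0.75 ± 0.15, and MAF5 was not called (0.23 ± 0.19, adjusted p = 0.360). In the FLC list 4 of 11 genes were higher and 1 lower, and the list did not pass (camera adjusted p = 0.0753).

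All 11 tested anthocyanin and flavonoid genes fell in nrpd1-3 (11 adjusted over the list alone), with a median log2 fold change of -2.16 (camera adjusted p = 4.99e-11). The dihydroflavonol reductase gene DFR fell from 55.3 ± 5.55 to 12.6 ± 0.955 CPM and LDOX from 40.4 ± 6.46 to 7.41 ± 0.977. Of 12 iron deficiency genes 11 fell (12 adjusted over the list alone; median -2.45, camera adjusted p = 1.45e-09), among them the regulators PYE (-2.07 ± 0.12) and BTS (-1.69 ± 0.13). Of 16 glucosinolate genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.75, camera adjusted p = 1.66e-06), with CYP79B2 at -1.26 ± 0.08 and its regulator MYB34 at -1.28 ± 0.10. Of 18 replication and mitosis genes 14 fell (14 adjusted over the list alone; median -0.49, camera adjusted p = 8.61e-06), including the cyclin gene CYCB1;2 (-0.75 ± 0.09) and the helicase gene MCM2 (-0.62 ± 0.10).

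A further 6 lists passed in nrpd1-3 with the preset correlation alone. Of 8 heat shock genes 7 fell (7 adjusted over the list alone; median -2.30, camera adjusted p = 8.57e-07; adjusted p = 0.106 with an estimated correlation), with HSP90.1 at -2.74 ± 0.13. Of 25 photosynthesis genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 0.000331; adjusted p = 0.225 with an estimated correlation). The light-harvesting gene LHCB1.4 rose from 336.9 ± 28.9 to 1771 ± 257.2 CPM and LHCA4 from 3448 ± 297.6 to 5672 ± 239.7, though reads of such families can be split between close paralogs. Of 20 jasmonate genes 11 fell and 4 rose (12 and 4 adjusted over the list alone; median -0.56, camera adjusted p = 0.0117; adjusted p = 0.117 with an estimated correlation). The storage protein gene VSP2 fell from 97.5 ± 0.828 to 15.7 ± 2.21 CPM and the synthesis gene AOC1, which has close paralogs, rose from 24.6 ± 2.36 to 75.6 ± 5.22. Of 22 abscisic acid and cold genes 11 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.53, camera adjusted p = 0.00494; adjusted p = 0.225 with an estimated correlation), with NCED3 at -2.71 ± 0.14. Of 12 touch and wound genes 8 fell (8 adjusted over the list alone; median -0.59, camera adjusted p = 0.00494; adjusted p = 0.225 with an estimated correlation), and TCH4 fell by 0.90 on the log2 scale. Of 8 phosphate genes 3 fell (3 adjusted over the list alone; median -0.63, camera adjusted p = 0.0332; adjusted p = 0.198 with an estimated correlation), the acid phosphatase gene PAP17 by the most, from 28.4 ± 3.15 to 4.86 ± 1.15 CPM; this call ended without the 3 libraries low in short transcripts.

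The other lists did not pass in nrpd1-3, with camera adjusted p-values from 0.0600 to 0.830. The salicylic acid list came closest, with 11 of 24 genes higher and 3 lower (12 and 3 adjusted over the list alone); LURP1 rose by 1.47 ± 0.16 and PR2 fell by 1.36 on the log2 scale. Genes of methylation pathways fell in part. ARGONAUTE4 (AGO4), the effector of RNA-directed DNA methylation, fell from 66.4 ± 4.15 to 41.1 ± 1.86 CPM and the methyltransferase gene CMT3 from 43.1 ± 2.86 to 29.3 ± 0.741, within lists of which 6 of 27 and 4 of 12 genes were lower and 2 and 1 higher (6 and 5 lower, 2 and 2 higher adjusted over the list alone). In demethylation 3 of 13 genes were lower, among them ROS1 and IDM3 (-0.79 ± 0.15), and among histone deacetylases 3 of 13 were lower and 1 higher. In the clock list 4 of 13 genes were higher and 2 lower, with PRR7 at 1.66 ± 0.13 and GI at -1.02 ± 0.16. SDC, FLC, LHCA4, PAP17 and IDM3 overlap another gene. Of root markers 1 of 4 and of floral organ markers 1 of 5 was lower, and FUS3 was not called (-0.52).

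Noncoding RNA genes were higher more often than other genes in nrpd1-3, 49 of 179 or 27.4% against 18.9% (odds ratio 1.62, Fisher's exact test, adjusted p = 0.0124). They were also lower less often, 7 of 179 or 3.91% against 19.3% (Fisher's exact test, adjusted p = 2.48e-08). AT4G13495 rose from 143.9 ± 16.1 to 587.6 ± 80.0 CPM and overlaps another gene, and AT4G04223 (chromosome 4, 2036511 to 2037816) rose from 2.75 ± 0.898 to 32.0 ± 3.25 CPM. The microRNA precursor MIR167d rose with a log2 fold change of 3.22 ± 0.40. Organelle genes were higher more often as well, 34 of 121 or 28.1% against 18.9% (adjusted p = 0.0282), and nrpd1-3 replicate 3 had the highest share of organelle counts, 0.257%. Their lower share was 1.65% against 19.2% (Fisher's exact test, adjusted p = 3.19e-08). The 18S ribosomal RNA locus AT3G41768 was called higher (1.88 ± 0.70, adjusted p = 0.0472) at 1711 ± 2219 CPM; this rests on replicate 3, without which the log2 fold change was -0.10 (adjusted p = 0.826). Higher genes lay within 3 Mb of a centromere at 9.26% against 8.05% of others (odds ratio 1.17, 95% interval 1.03 to 1.32; Fisher's exact test, adjusted p = 0.0329) and lower genes at 7.22% against 8.53% (odds ratio 0.834, adjusted p = 0.0223). With a 5 Mb window the call for higher genes ended (odds ratio 1.07, unadjusted p = 0.132). The limits of the centromere test given for hda6 hold here too, also for the shares of noncoding RNA genes.

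**Figure D3:**
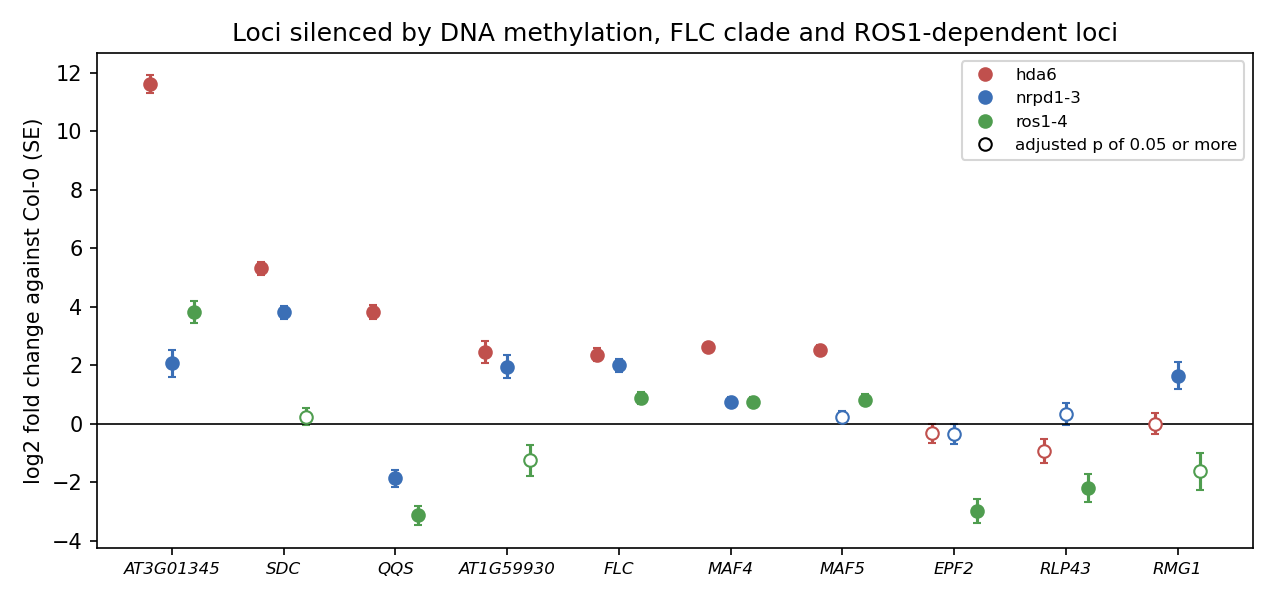
Log2 fold change against Col-0, with its SE, of 4 loci silenced by DNA methylation, of FLC, MAF4 and MAF5 and of 3 loci known to need ROS1, in the 3 mutants; open points did not pass the test. AT3G01345 was higher in all 3 mutants, by 11.6 in hda6, 2.06 in nrpd1-3 and 3.81 in ros1-4, and EPF2 was called in ros1-4, at -2.99.

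In ros1-4, 18 of 24 salicylic acid genes, the 12 tested touch genes and 11 of 12 iron deficiency genes fell, as did 2 of the 3 tested loci known to need ROS1, and 5 genes read in all other genotypes had no count at all. The call of the list of loci known to need ROS1 was lost with an estimated correlation (adjusted p = 0.0740). EPF2 (AT1G34245, chromosome 1, 12472868 to 12473974) fell from 5.27 ± 0.455 to 0.674 ± 0.354 CPM, the nucleoside transporter gene ENT6 from 14.6 ± 0.0672 to 0.268 ± 0.0471 CPM, and PR1 from 36.0 ± 4.45 to 1.09 ± 0.354 CPM. BT2, a nitrate- and sugar-responsive scaffold gene, rose from 3.91 ± 0.498 to 66.8 ± 9.10 CPM. In all, 2904 of 20023 genes were changed, 1200 higher and 1704 lower, of which 237 and 711 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg).

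Of the 3 tested loci known to need ROS1, EPF2 (-2.99 ± 0.41, adjusted p = 0.000175) and RLP43 (-2.20 ± 0.47, adjusted p = 0.00571) fell, and RMG1 had a log2 fold change of -1.63 ± 0.63 (adjusted p = 0.109). The list's median was -2.20, with 3 lower adjusted over the list alone (camera adjusted p = 0.00599; adjusted p = 0.0740 with an estimated correlation). Of the silenced loci, AT3G01345 rose to 2.36 ± 0.299 CPM (3.81 ± 0.37) and QQS fell to 0.462 ± 0.240 CPM (-3.14 ± 0.34), while SDC (0.24 ± 0.29) and AT1G59930 (-1.25 ± 0.53) were not called; over the list alone 1 was higher and 2 lower, and the list did not pass (camera adjusted p = 0.948).

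Among the other rises in ros1-4 were the kinase gene CPK22, from 0.232 ± 0.179 to 4.71 ± 0.398 CPM (4.42 ± 0.39), the cytochrome P450 gene CYP81D11, from 0.933 ± 0.171 to 9.19 ± 1.11 CPM, and the Kelch repeat F-box genes AT1G23390, from 19.0 ± 1.79 to 139.9 ± 15.1 CPM, and AT1G80440, from 5.36 ± 0.112 to 36.5 ± 1.3 CPM. Some genes had no count in ros1-4. AT2G32200 (chromosome 2, 13676389 to 13677306), at 4.87 ± 0.457 CPM in Col-0, was at least 133.4-fold lower, the neighbours AT3G09160 (chromosome 3, 2805779 to 2807055) and AT3G09162 (chromosome 3, 2807214 to 2808327), at 2.72 ± 0.701 and 1.97 ± 0.428 CPM in Col-0, at least 72.5- and 52.8-fold lower, and the noncoding RNA AT1G67105, at 0.696 ± 0.125 CPM, at least 18.8-fold lower. With the lectin receptor kinase gene AT3G45390 these made up the 5 genes that had no count in the 3 libraries of a single genotype and at least 10 in each of the other 9; all 5 were at 0 in ros1-4, where 3 counts correspond to 0.0363 CPM. AT1G08940 had a ratio of Col-0 to ros1-4 of 85.5 (95% counting interval 23.3 to 711.5), and the receptor kinase gene CRK41 fell from 22.7 ± 2.06 to 0.385 ± 0.0847 CPM.

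Of 24 salicylic acid genes 18 fell in ros1-4 (19 adjusted over the list alone; median -1.28, camera adjusted p = 3.62e-15), with PR1 at -5.04 ± 0.21, PR2 at -1.77 ± 0.09 and the regulator SARD1 at -2.46 ± 0.15. Of 12 touch and wound genes 12 fell (12 adjusted over the list alone; median -1.36, camera adjusted p = 1.73e-13), including DREB26 (-2.04 ± 0.10) and WRKY33 (-1.89 ± 0.16). Of 12 iron deficiency genes 11 fell (12 adjusted over the list alone; median -1.64, camera adjusted p = 7.00e-12), with BHLH100 at -5.08 ± 0.47 and BHLH39 at -4.91 ± 0.58. Of 16 glucosinolate genes 12 fell (14 adjusted over the list alone; median -0.57, camera adjusted p = 4.84e-10), among them CYP79F1 (-1.29 ± 0.10).

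A further 4 lists passed in ros1-4 with the preset correlation alone. Of 8 heat shock genes 6 fell (6 adjusted over the list alone; median -1.36, camera adjusted p = 2.84e-06; adjusted p = 0.0984 with an estimated correlation), HSFA2 by 2.67 on the log2 scale. Of 8 phosphate genes 5 rose (6 adjusted over the list alone; median 0.54, camera adjusted p = 0.00456; adjusted p = 0.0971 with an estimated correlation), with the transporter gene PHT1;4 at 1.51 ± 0.20. Of 13 clock genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.00397; adjusted p = 0.139 with an estimated correlation), and RVE1 rose from 84.2 ± 3.98 to 228.7 ± 9.35 CPM. Of 11 anthocyanin genes 2 rose (4 adjusted over the list alone; median 0.22, camera adjusted p = 0.0466; adjusted p = 0.106 with an estimated correlation), including the regulator PAP1 (0.77 ± 0.17); this call ended without the 3 libraries low in short transcripts.

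The other lists did not pass in ros1-4, with camera adjusted p-values from 0.144 to 0.991. Of 20 jasmonate genes 5 rose and 10 fell (6 and 10 adjusted over the list alone). The synthesis gene LOX2 rose from 654.5 ± 17.0 to 2073 ± 166.0 CPM, while the signalling gene JAZ5 fell from 49.6 ± 4.17 to 17.3 ± 1.79. Of 22 abscisic acid and cold genes 2 rose and 6 fell (3 and 7 adjusted over the list alone), with NCED3 at -2.24 ± 0.13 and RD26 at 1.19 ± 0.11. In the FLC list 4 of 11 genes rose and 3 fell. FLC rose to 4.34 ± 0.923 CPM (0.88 ± 0.21, adjusted p = 0.0128; 0.0656 without Col-0 replicate 2 and 0.0595 without ros1-4 replicate 2), MAF4 by 0.75 ± 0.15 and MAF5 by 0.82 ± 0.18. FUL, SOC1 and FT, which promote flowering, fell by 2.19, by 0.93 and by 2.21 on the log2 scale. No gene was called in the lists of DNA demethylation (13 tested), RNA-directed DNA methylation (27), methylation maintenance (12), histone deacetylases (13), and replication and mitosis (18), and 1 of 25 photosynthesis genes rose. Of organ markers, 1 of 4 root genes rose and 1 fell, 1 of 5 floral genes rose and 1 fell, and FUS3 fell, with a ratio of Col-0 to ros1-4 of 11.7 (95% counting interval 2.89 to 101.8; adjusted p = 0.0333, and 0.139 without Col-0 replicate 2).

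Neither higher nor lower genes of ros1-4 passed the test for lying within 3 Mb of a centromere (Fisher's exact test, adjusted p = 0.705 for both). Their odds ratios were 0.951 (95% interval 0.758 to 1.18) and 1.04 (0.867 to 1.25). Noncoding RNA genes were higher less often than other genes, 1 of 179 or 0.559% against 6.04% (Fisher's exact test, adjusted p = 0.00110). AT4G04223 fell from 2.75 ± 0.898 to 0.168 ± 0.0270 CPM (-4.01 ± 0.36). Of the genes named for ros1-4, CYP81D11, AT3G09160, ENT6, SARD1, WRKY33, RVE1, SDC and FLC overlap another gene.

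**Figure D4:**
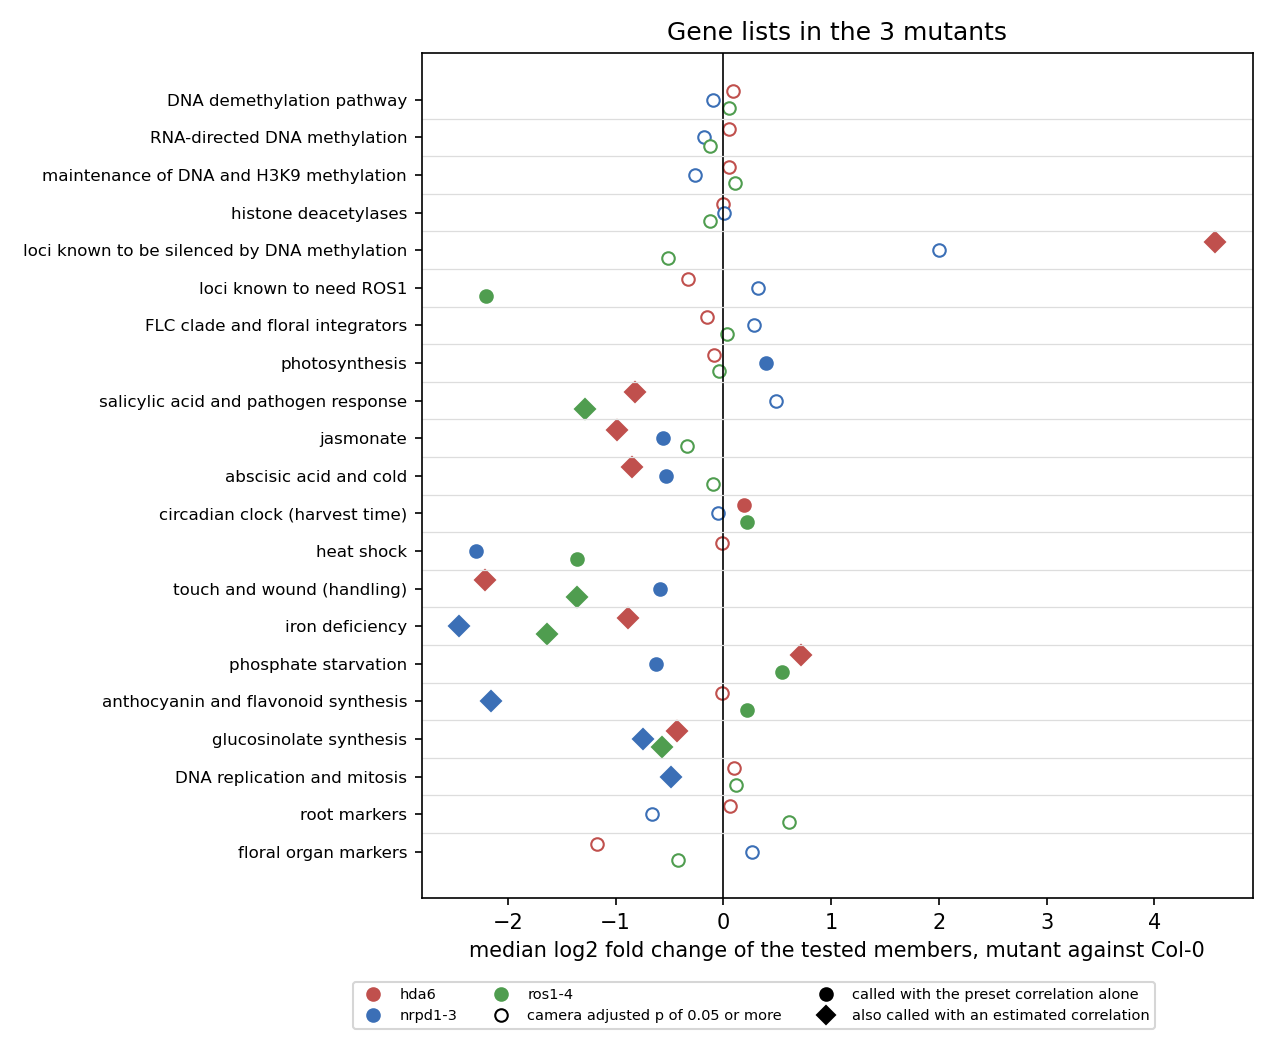
Median log2 fold change against Col-0 of the tested members of each gene list with at least 3 of them, in the 3 mutants; open circles did not pass camera, filled circles passed with the preset correlation alone and diamonds also with an estimated correlation. Touch and wound genes lay at -2.21 in hda6, -0.59 in nrpd1-3 and -1.36 in ros1-4, and loci silenced by DNA methylation at 4.56 in hda6.

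With the preset correlation 9 lists passed in hda6, 10 in nrpd1-3 and 9 in ros1-4, and with an estimated correlation 8, 4 and 4 did. Those that held were, in hda6, all but the clock, in nrpd1-3 anthocyanin, iron deficiency, glucosinolate and replication with mitosis, and in ros1-4 salicylic acid, touch, iron deficiency and glucosinolate. Their camera adjusted p-values were then larger. They went from 2.04e-16 to 0.00747 for touch genes in hda6 and from 4.99e-11 to 0.00150 for anthocyanin genes in nrpd1-3. For salicylic acid genes in ros1-4 the change was from 3.62e-15 to 0.000362. Splits that mixed the libraries of both genotypes passed up to 8, 9 and 8 lists with the preset correlation. The real counts were hardly above these. Each of those splits keeps part of the difference between the genotypes, and lists can pass from it. Their counts therefore do not measure how many lists pass without a difference, and the comparison decides nothing about the real groups.

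The mutants shared many changed genes. In all 3, 286 genes were higher and 590 lower, where independent lists would share 22.2 and 33.2, and simulated unchanged genotypes against the same Col-0 libraries shared 0 at most. Unchanged genotypes give almost no calls, so that 0 does not measure how much of the sharing came from the shared controls. With the length correction 437 genes were higher in all 3, against 44.1 expected. Genes higher in all 3 included PORB of chlorophyll synthesis, at 57.2 ± 1.94 CPM in Col-0 and 119.7 ± 8.51, 170.2 ± 5.44 and 117.0 ± 10.4 CPM in hda6, nrpd1-3 and ros1-4, the growth regulator HBI1 (log2 fold changes 1.05, 1.83 and 1.41) and LHCB1.4. Genes lower in all 3 included the ubiquitin ligase gene PUB19, at 99.4 ± 3.10 CPM in Col-0 and 9.99 ± 0.704, 10.5 ± 0.553 and 30.1 ± 0.392 CPM in the mutants, SAG29, NCED3 and JAZ5.

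For hda6 and nrpd1-3, 791 genes were higher in both and 972 lower in both, with 369.6 and 390.5 expected of independent lists, and 318 changed in opposite directions against 759.9 expected. Without the 3 libraries low in short transcripts 711 were opposite, against 1170 expected. AT3G29639 and AT5G24240 stood out among those higher in both and not in ros1-4, at 31.1 ± 1.46 and 28.9 ± 2.79 CPM in hda6, 73.6 ± 6.77 and 20.5 ± 3.68 in nrpd1-3, and 0.450 ± 0.130 and 0.241 ± 0.0594 in Col-0. For hda6 and ros1-4, 476 genes were higher and 884 lower in both, with 117 and 174 expected, and 113 were opposite against 288 expected, or 184 against 439.6 without those 3 libraries. PR1 and WRKY18 were lower and the lectin gene AT1G52000 and MBP1, which bind myrosinase or sugars, were higher in this pair; PR1 stood at 42.5 ± 5.79 CPM in nrpd1-3, a log2 fold change of 0.24. For nrpd1-3 and ros1-4, 612 were higher and 966 lower in both, with 228 and 326 expected, and 339 were opposite against 553 expected; the trehalose phosphate synthase gene TPS11 (3.18 and 1.69) was higher and the ammonium transporter gene AMT1;2 (-1.92 and -2.42) lower in both. Of genes changed at least 2-fold in both mutants, 46, 32 and 56 were opposite in these 3 pairs, against 67.7, 32.4 and 49.9 expected. Across all tested genes, which are not independent replicates, fold changes correlated at 0.338, 0.310 and 0.321 for these pairs, where shared Col-0 libraries alone gave 0.511, 0.511 and 0.496 in 50 simulations. The covariances were 0.249, 0.175 and 0.156, against 0.0394, 0.0396 and 0.0395 simulated. The controls were not split, since 3 Col-0 libraries do not give each part at least 2, so part of the excess may come from the shared controls.

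The mutants also differed from each other. Between hda6 and nrpd1-3 8313 genes differed (4138 higher in hda6), between hda6 and ros1-4 3191 (1831 higher in hda6), and between nrpd1-3 and ros1-4 6873 (3596 higher in nrpd1-3) by the same edgeR test. Salicylic acid genes were higher in nrpd1-3 than in ros1-4, 22 of 24 (22 adjusted over the list alone, median 1.65, camera adjusted p = 1.79e-12). Of these 24, 19 were lower and 3 higher in hda6 than in nrpd1-3 (19 and 3 adjusted over the list alone, median -1.06, camera adjusted p = 1.52e-06). Anthocyanin genes were lower in nrpd1-3 than in ros1-4, 10 of 11 (11 adjusted over the list alone; median -2.39, camera adjusted p = 8.96e-13), and 10 of 11 were higher in hda6 than in nrpd1-3 (10 adjusted over the list alone; median 2.15, camera adjusted p = 8.80e-10). All 8 phosphate genes were higher in hda6 than in nrpd1-3 (8 adjusted over the list alone; median 2.28, camera adjusted p = 4.52e-06), and all 4 silenced loci were higher in hda6 than in ros1-4 (4 adjusted over the list alone; median 6.01, camera adjusted p = 3.29e-08). These list differences also passed with an estimated correlation.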

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

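The halved counts, the length correction and the test without hda6 replicate 2, nrpd1-3 replicate 3 and ros1-4 replicate 3 were chosen after the data were seen. Named genes were counted here without ROS1, NRPD1 and HDA6 and without those chosen only from an overlap set. Of those called, 72 of 89 in hda6, 97 of 106 in nrpd1-3 and 65 of 77 in ros1-4 stayed so. They were called in the same direction under every alternative that tested them. The counts of changed genes stayed within 1.5 times under other size factors, no filter, DESeq2, limma-trend, no organelle genes and the robust fit. With the pair of genotypes alone 5997, 5904 and 2790 genes changed in hda6, nrpd1-3 and ros1-4. The main test gave 3991, 7626 and 2904. With the pair alone, nrpd1-3 thus had no more changed genes than hda6. The cause was not tested. Leaving out 1 replicate gave 2639 (without hda6 replicate 1) to 3150 for hda6, 6361 to 7814 for nrpd1-3 and 2183 to 2316 for ros1-4, with fewer samples. Without the 3 libraries low in short transcripts the counts were 5355, 8815 and 3337. Limma-trend on the deposited signal gave 712, 1175 and 521 genes changed at least 2-fold in hda6, nrpd1-3 and ros1-4; the test, the values and the offset of 1 changed together, and the cause was not tested. With an estimated correlation 4 lists passed in nrpd1-3 and 4 in ros1-4.

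NRPD1 in ros1-4 against Col-0 passed with library size alone (-0.42, adjusted p = 0.0487), with the replicate block (-0.42, adjusted p = 0.0302), with the length correction (-0.49, adjusted p = 0.00938) and without the 3 libraries (-0.55, adjusted p = 0.00910). Leaving out 1 replicate gave -0.54 (without ros1-4 replicate 3, adjusted p = 0.02003) to -0.27 (without ros1-4 replicate 1), and over all alternatives the adjusted p ran from 0.00910 to 0.227. Without the 3 libraries, ROS1 in ros1-4 stood at -0.30 (adjusted p = 0.0401), NRPD1 in nrpd1-3 at -0.34 (adjusted p = 0.0435) and NRPD1 in hda6 against ros1-4 at 0.45 (adjusted p = 0.0330); for the last, leaving out 1 replicate gave 0.18 to 0.45 (without ros1-4 replicate 3, adjusted p = 0.0379). HDA6 in hda6 ranged from 0.33 to 0.46 when 1 replicate was left out. For these the cause was not tested. The ribosomal RNA AT3G41768 in nrpd1-3 ranged from -0.10 (without nrpd1-3 replicate 3) to 2.38 and stood at -0.11 without the 3 libraries.

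At least 2-fold in both mutants, 199 genes were higher, 232 lower and 46 opposite in hda6 and nrpd1-3, 84, 327 and 32 in hda6 and ros1-4, and 126, 255 and 56 in nrpd1-3 and ros1-4, and 44 were higher and 160 lower in all 3, since fewer genes enter. Independent lists of that size would give 67.7, 32.4 and 49.9 opposite genes. Without the 3 libraries 711 genes were opposite in hda6 and nrpd1-3 (1170 expected) and 184 in hda6 and ros1-4 (439.6 expected), and with the length correction 437 were higher in all 3 (44.1 expected); the cause was not tested. Within 5 Mb of a centromere the odds ratio of genes higher in nrpd1-3 was 1.07.

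With the replicate number as a block, 4355, 7808 and 2970 genes changed in hda6, nrpd1-3 and ros1-4. The numbers did not pair samples across all genotypes: deviations of libraries with the same number correlated above 0.1 in 5 of 18 pairs (-0.193 to 0.535), and 5 of 12 libraries fitted best with their own number. In nrpd1-3 and ros1-4 all 3 pairs with the same number were above 0.1 (0.310, 0.152 and 0.535), and pairs with different numbers ran from -0.481 to 0.283. Deviations sum to 0 within a genotype, so these pairs are not independent and do not show pairing by number. For nrpd1-3 replicate 2 the correlation with ros1-4 replicate 1, 0.163, was above the 0.152 with ros1-4 replicate 2. In simulated counts, 34.3% of 1.5-fold changes were recovered in hda6. That simulation gave 139 calls for hda6 against Col-0, where the data gave 3991. The adjusted p depends on how many genes change, so the share recovered may differ in the data. Depth was not varied apart from the spread between libraries, so its part in the 34.3% was not tested.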

Other observations

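The tests for RNA of hda6 plants and for handling of Col-0 alone were chosen after their result was seen, and so were the sugar starvation list and the genes named next.

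Some genes changed in opposite directions between mutants. The noncoding RNA AT4G04223 stood at 2.75 ± 0.898 CPM in Col-0, 27.5 ± 6.0 in hda6, 32.0 ± 3.25 in nrpd1-3 and 0.168 ± 0.0270 in ros1-4. The beta-glucosidase gene BGLU18, which releases abscisic acid from its glucose ester, rose from 787.9 ± 20.4 to 1818 ± 101.5 CPM in hda6 and fell to 262.7 ± 18.8 CPM in ros1-4. The receptor kinase gene CRK23 rose by a log2 fold change of 1.85 in hda6 and fell by 1.21 in nrpd1-3 and by 2.54 in ros1-4. The disease resistance gene AT5G36930 rose from 26.6 ± 0.217 to 61.9 ± 1.81 CPM in nrpd1-3 and fell to 9.79 ± 0.815 CPM in ros1-4. The flowering repressor SMZ fell from 12.6 ± 0.916 to 6.15 ± 1.03 CPM in nrpd1-3 and rose to 32.3 ± 2.54 CPM in ros1-4, and BT1, a relative of BT2, moved the same way, with log2 fold changes of -0.86 and 1.08.

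Of 12 tested genes of sugar starvation and darkness, 11 rose and 1 fell in nrpd1-3, with a median log2 fold change of 1.86. The list was built after large rises such as that of SEN1, a member, had been seen, so no test of the list is given. The proline dehydrogenase gene ProDH1 rose from 16.2 ± 0.653 to 264.2 ± 54.0 CPM, the branched-chain amino acid gene MCCA from 17.8 ± 0.592 to 51.0 ± 1.27 CPM and the trehalose phosphate synthase gene TPS8 from 49.1 ± 1.23 to 192.6 ± 29.1 CPM, while DIN9 fell by 0.92 on the log2 scale. In hda6 3 genes rose and 1 fell, with a median of 0.10, and in ros1-4 4 rose, with a median of 0.28.

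A first pattern was that short transcripts were low together in ros1-4 replicate 3, nrpd1-3 replicate 3 and hda6 replicate 2. A length trend of each library was not the whole of it: with the trend removed, deviations of the ros1-4 and nrpd1-3 libraries still correlated at 0.455, against 0.535 before. RNA of hda6 plants in ros1-4 replicate 3 was excluded at any large share, since 52 genes stood there at 0.0433% of their hda6 level. They were chosen as read in hda6 and nearly absent from the other 8 libraries, with ros1-4 replicate 3 left out of the choice. The labels give no group for these libraries, so no biological explanation was tested.

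A second pattern was that touch and wound genes were lower than in Col-0, 12 of 12 in hda6 and in ros1-4, with medians of -2.21 and -1.36, and 8 of 12 in nrpd1-3, with a median of -0.59, members up to 0.49, and adjusted p = 0.225 with an estimated correlation (camera). Different handling of the Col-0 plants alone would leave the mutants alike, but hda6 lay below nrpd1-3 with a median of -1.46, and 12 of 12 genes passed. Handling of the Col-0 plants as part of the cause, beside a difference between the mutants, remains open. A transcript length trend did not account for the lower touch and wound genes, with a median in hda6 of -2.10 after the correction against -2.21 before. Handling that differed between all genotypes remains open, as does an effect of the mutations, because each genotype may have been grown and harvested as a unit.

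A further pattern was the rise of sugar starvation and darkness genes in nrpd1-3. With the length correction the median was 1.85 against 1.86 before, so a transcript length trend did not account for it. Another time of day at harvest could not be told: morning minus evening clock genes gave -0.29 ± 0.46 (SE over 11 genes), with PRR5 at 2.01 and GI at -1.02. Less light or sugar in the nrpd1-3 plants and an effect of the mutation were not tested apart.

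Exchanging libraries between the groups of each comparison allows 10 splits, too few for a share under 0.05. Every split but the real one mixes both genotypes in each group, so their difference adds to the spread within groups. Low gene counts in those splits therefore do not measure how many calls arise without a difference between genotypes. Changed genes and genes changed at least 2-fold were counted over the splits of all 6 comparisons, and gene lists over those of the 3 with Col-0. In each of these, 1 of 10 splits, the real one, gave a count as large as the real count. By edgeR, 3991, 7626 and 2904 genes changed in hda6, nrpd1-3 and ros1-4 (1329, 2046 and 948 at least 2-fold) and 8313, 3191 and 6873 between hda6 and nrpd1-3, hda6 and ros1-4, and nrpd1-3 and ros1-4 (2324, 1150 and 1873 at least 2-fold), and the highest other split gave 0 in each. With an unadjusted p under 0.05 there were 6812, 9448 and 5361 genes against Col-0, where the highest other split gave 979, 1605 and 797, and 9923, 5819 and 8762 between mutants, against 2531, 1349 and 3229. For gene lists the real split gave 9, 10 and 9, and the highest other split gave 8, 9 and 8. Part of the difference between genotypes remains in those splits, so these list counts do not measure how many lists pass without it either.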
